A study of Mus musculus with 9 samples.

How the data were processed

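The series used female EL16.7 mouse embryonic stem cells at day 7 of differentiation. This line is a hybrid of the CAST/Ei and 129/Sv/Jae strains, per the labels. In dCLIP, cells carried the biotin ligase BirA and an Avi-GFP-tagged subunit of Polycomb repressive complex 2 (PRC2), either EZH2 or SUZ12. Protein and RNA were crosslinked with UV light, lysates were treated with DNase and RNase, and tagged complexes were captured on streptavidin under stringent washes before small-RNA libraries were made, per the labels' protocols. The 9 samples were 2 EZH2 and 2 SUZ12 dCLIP libraries, each from a different stable clone, 1 mock dCLIP library from cells with an empty vector, and 4 PRO-seq libraries, 2 of wild-type cells and 2 of a SUZ12 degron line. PRO-seq maps engaged RNA polymerase. The mock and PRO-seq libraries were not analysed here.

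The data consisted of 8 peak lists, 1 per dCLIP library and strand, so peaks had been called on each library alone and not on pooled libraries. Each list gave the chromosome, start, end, strand and summit of a peak, and the p-value and false discovery rate (FDR) that the authors' peak caller had assigned, in the deposited lists. Peak names carried the prefix of the caller PeakRanger. Its version, its settings and whether the mock library served as control were not given in the sources used here. The submitters' processing notes name Trim Galore 0.3.3, TopHat2 2.0.8, SAMtools 0.1.18, bedtools 2.17.0 and the mouse build mm9. Of 49266 peaks, 0 ended beyond a chromosome of mm9 and 368 beyond a chromosome of GRCm38, so coordinates are given in mm9, counted from 1. The p-values reached at most 0.00991 in any list. In the comparisons between libraries and proteins, the FDR and p of a peak were used only to describe and rank peaks within a library. Sites are also described by fixed FDR limits applied to each library, and the closing tests use p-values pooled over libraries.

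The annotation at hand was of GRCm38 and no genome sequence was used, so peaks were not assigned to genes, exons or introns and no sequence was extracted. The planned gene lists, locations within transcripts and sequence composition were therefore not analysed here. Regions are named by coordinates, by a rule set before the data were examined: the 10 windows of 50 kb, counted per strand, with the highest minimum number of peaks over the 4 libraries, with ties settled by the sum, and any 1-Mb window past the threshold of the test between proteins. The ranking of single sites by their weakest FDR, the FDR deciles and the 100 best peaks per library were chosen after the data were seen.

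Peaks on the same strand that overlapped by at least 1 bp counted as shared. The share of peaks of a library overlapped by another library was averaged over both directions. It was set against 100 random placements of the second list on the same chromosome and strand, and against 100 local shifts of its peaks by 5 to 50 kb. Consensus sites of a protein were merged intervals of peaks found in both of its clones. Overlapping peaks of all 4 libraries were merged into sites by strand. Merging joins peaks in chains, so the peaks of a site need not all overlap each other. The Jaccard index was the number of bases covered in both libraries over the bases covered in either. Its mean within proteins minus its mean between proteins was tested by an exact permutation test over the 3 ways to split 4 libraries into pairs, which allows no two-sided p below 0.333. The chromosome X share was tested over the same splits.

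Peaks were counted by summit in 1-Mb windows per strand. Windows with a mean of at least 5 peaks were compared as log2((peaks + 0.5) / (peaks in the library + 1) x 10000) between SUZ12 and EZH2 with limma-trend, two-sided, with Benjamini-Hochberg adjustment at 0.05. Numbers of peaks are not reads, so no read-count model was used. Alternatives covered a 50% reciprocal overlap, summits within 100 bp, peaks set to 100 bp, the 50% of each list with the lowest FDR, equal list lengths, the opposite strand, other offsets, filters, scalings and window sizes, the replicate number as a block, and leaving out each library.

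Analyses ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and in R 4.3.3 with limma 3.58.1. Chromosome lengths came from GenomeInfoDb 1.38.1. On simulated lists of 10468 peaks with 10% of peaks planted as shared, the overlap step found 10.1%, with 0.0985% by chance. For the test between proteins, peaks per window were simulated with Poisson noise around the real means, and 870 windows were tested. Of these, 50, 49, 50 and 50 were changed 2-, 4-, 8- and 16-fold, with no further spread between clones. limma called 38% of windows changed 2-fold, 89.8% of those changed 4-fold and 1 of 671 unchanged windows.

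Read depth cannot be read from peak lists. The precision of a share is therefore given by the number of peaks in the library, 10468 to 13951, as a 95% Wilson interval. Such intervals cover counting error only, since peaks of a library are not independent and reads without molecular identifiers can be copies.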

Results

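RNA sites of the PRC2 subunits EZH2, the histone methyltransferase, and SUZ12, a core subunit needed for its activity, were mapped by dCLIP in differentiating female mouse embryonic stem cells. There were 2 clones for each protein. The EZH2 lists held 10468 peaks in replicate 1 and 13267 in replicate 2, a mean of 11868 ± 1979 (SD, n = 2). The SUZ12 lists held 11580 and 13951 peaks, a mean of 12766 ± 1677 (SD, n = 2), so the difference between the proteins was smaller than the spread between clones. Peaks covered 1868 and 2489 kb in the EZH2 libraries and 1889 and 1977 kb in the SUZ12 libraries. Between 50.7% and 53.5% of the peaks of a library lay on the plus strand. EZH2 peaks were wider, with a median width of 182.5 ± 7.78 bp (SD, n = 2) against 144.5 ± 9.19 bp for SUZ12, a gap larger than the spread between clones. The widths were not tested. With 2 clones per protein an exact permutation test would allow no p below 0.333, and the reason for the gap was not examined. Background in the mock library was not analysed here, so the lists are compared with each other and with chance and not with an untagged control.

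Peaks were concentrated in stretches that recurred in every library. The 50-kb window with the highest minimum lay on the plus strand of chromosome 4 at 137050001 to 137100000 and held 9 and 7 EZH2 peaks and 8 and 8 SUZ12 peaks. Chromosome 8 contributed 4 of the 10 leading windows, all on the plus strand. The window at 109150001 to 109200000 held 6 peaks in each EZH2 library and 6 and 8 in the SUZ12 libraries, and the window at 87550001 to 87600000 held 5, 7, 10 and 7 peaks in the order EZH2 replicates 1 and 2, SUZ12 replicates 1 and 2. In the same order, the window at 86400001 to 86450000 held 5, 6, 7 and 6 peaks, and that at 46100001 to 46150000 held 6, 6, 5 and 6.

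On the minus strand of chromosome 15, the window at 98650001 to 98700000 held 6, 6, 6 and 7 peaks. The plus strand of chromosome 7 at 134900001 to 134950000 held 7, 5, 6 and 6. Chromosome 6 had a plus-strand window at 125050001 to 125100000 with 4, 8, 11 and 9 peaks and a minus-strand window at 122650001 to 122700000 with 7, 6, 11 and 4. The last of the 10, on the plus strand of chromosome 10 at 118900001 to 118950000, held 4, 7, 5 and 11 peaks. Of 16871 windows with any peak, 2118 had a peak in every library, 370 had at least 2 and 37 at least 4. Random placement gave a mean of 22.5 windows with a peak in every library and 0 with at least 2, over 20 placements. These placements covered transcribed and untranscribed sequence alike, so the recurrence is not shown to go beyond regions with RNA.

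**Figure D1:**
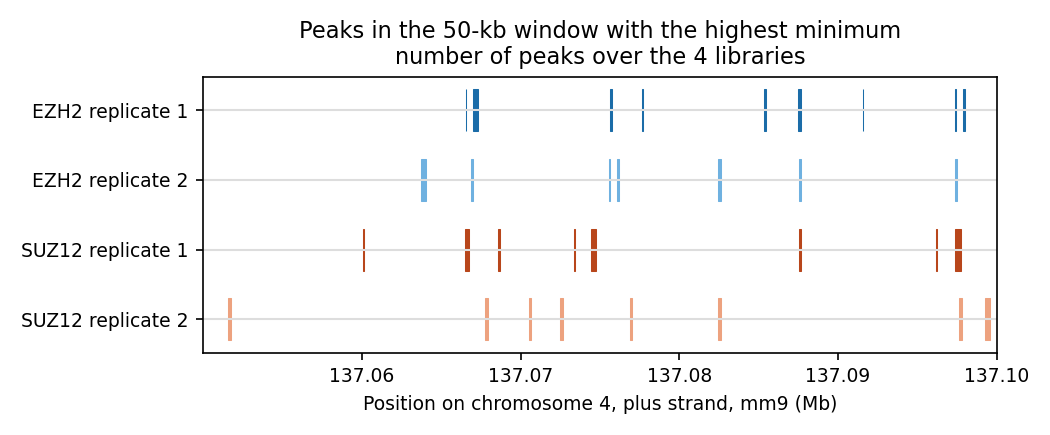
Peaks of each of the 4 libraries on the plus strand of chromosome 4 (mm9, position in Mb) in the 50-kb window with the highest minimum number of peaks, with bars drawn to scale from start to end of each peak. The libraries hold 9, 7, 8 and 8 peaks, spread over most of the window and only partly at the same positions.

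The agreement between clones of a protein was compared first, because each clone is an independent cell line. In EZH2, 9.85% of the 10468 peaks of replicate 1 (95% Wilson interval 9.29 to 10.4%) were overlapped on the same strand by replicate 2, and 7.79% (7.35 to 8.26%) in the other direction. In SUZ12 the shares were 9.64% (9.11 to 10.2%) and 7.99% (7.55 to 8.45%). The means of both directions, 8.82% for EZH2 and 8.81% for SUZ12, were 96.0 and 111 times the level of random placement, 0.0919% and 0.0793%, and exceeded all 100 placements. Local shifts of 5 to 50 kb gave 0.565% and 0.511%, so the shares were 15.6 and 17.2 times the local level. Both kinds of placement can put peaks on untranscribed sequence, so these excesses do not separate binding from the presence of RNA. On the opposite strand the shares were 0.132% for EZH2, within the range of random placement, and 0.138% for SUZ12, where the highest of its 100 placements was 0.135% and another set of 100 reached 0.190%.

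Sharing rose with peak strength. Among peaks in the decile with the lowest FDR, a mean of 30.9% were found in the other clone of the same protein, against 4.55% in the decile with the highest FDR. Of the 100 peaks with the lowest FDR in a library, between 74% and 88% were found in the other clone. Widely shared peaks were also wider, and wider peaks meet a 1-bp overlap more easily. Peaks found in all 4 libraries had median widths of 226 and 232 bp in EZH2 and 212.5 and 180 bp in SUZ12. Peaks found in 1 library had 173 and 186 bp in EZH2 and 148 and 137 bp in SUZ12. Strength and width were not separated here.

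**Figure D2:**
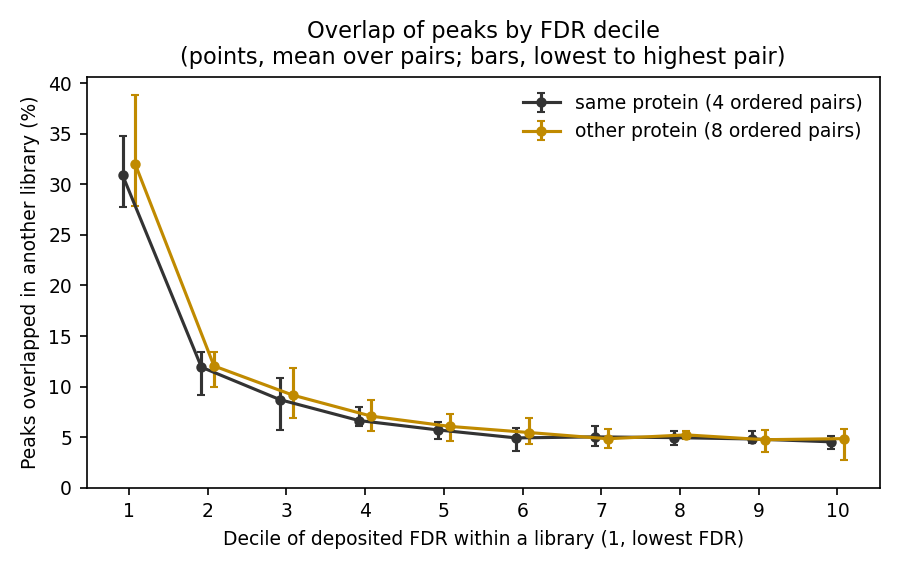
Percentage of peaks overlapped on the same strand in another library (vertical axis) by decile of deposited FDR within a library (horizontal axis, 1 is the lowest FDR), as the mean over 4 ordered pairs of the same protein and 8 ordered pairs of different proteins, with bars from the lowest to the highest pair. Means fall from 30.9% to 4.55% for the same protein and from 32.0% to 4.86% for different proteins.

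As both proteins belong to one complex, the sites of EZH2 were compared with those of SUZ12. Both clones of EZH2 shared 1025 consensus sites and both clones of SUZ12 shared 1110. Of the EZH2 sites, 387 (37.8%, Wilson interval 34.8 to 40.8%) were overlapped by a SUZ12 consensus site, and 390 of the SUZ12 sites (35.1%, 32.4 to 38.0%) by an EZH2 consensus site. The mean of 36.4% stood against 0.0169% with random placement and 0.126% with local shifts, and exceeded all 100 placements of each kind. Both kinds can put sites on untranscribed sequence, so the excess does not separate shared binding from the presence of the same RNA in all libraries. Splitting the libraries across proteins gave similar values, 34.3% when EZH2 replicate 1 was joined with SUZ12 replicate 1 and 36.0% when it was joined with SUZ12 replicate 2.

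Merging all peaks gave 44277 sites, of which 402 (0.908%) had a peak in all 4 libraries. Random placement gave at most 1 such site and local shifts at most 2, but neither was limited to transcribed sequence, so abundant RNA is not told apart from binding. Of the 402 sites, 209 lay on the plus strand and 22 on chromosome X, and their median length was 290 bp. They include a site on chromosome Y and sites of 7975, 7651 and 9088 bp that end on a multiple of 10 kb, features flagged below. Another 539 sites were found in 3 libraries, 2637 in 2 and 40699 (91.9%) in 1.

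The strongest of the 402 sites lay on the plus strand of chromosome 7 at 89919464 to 89920618, 1155 bp long. Its FDR was 2.68e-51 and 3.36e-63 in the EZH2 libraries and 1.90e-54 and 2.01e-64 in the SUZ12 libraries. The next site, on the minus strand of chromosome 9 at 56071336 to 56071823, had an FDR of at most 3.59e-24 in every library. Sites on the minus strands of chromosome 12 at 81542289 to 81542578, chromosome 1 at 115800478 to 115800952 and chromosome 7 at 7230582 to 7230857 had an FDR of at most 2.02e-23, 3.24e-21 and 1.13e-20 in every library. They were followed by plus-strand sites of chromosome 16 at 17222326 to 17222660 and at 23111340 to 23111805, with at most 1.71e-17 and 2.33e-17, and a minus-strand site of chromosome 4 at 45359304 to 45359662, with at most 3.02e-17. In all, 32 of the 402 sites had an FDR below 1e-10 in each library. The stretch of the strongest site on chromosome 7 had peaks on both strands in every library. Its minus strand held another of the 402 sites, at 89920112 to 89920576, with an FDR of at most 0.000238.

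Sites restricted to a protein were compared with sites restricted to the other pairs of libraries. Both EZH2 libraries and no SUZ12 library had a peak at 364 sites, and both SUZ12 libraries and no EZH2 library at 461, a sum of 825. Both other pairings gave higher sums, 962 when libraries were paired by replicate number and 850 when EZH2 replicate 1 was paired with SUZ12 replicate 2.

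**Figure D3:**
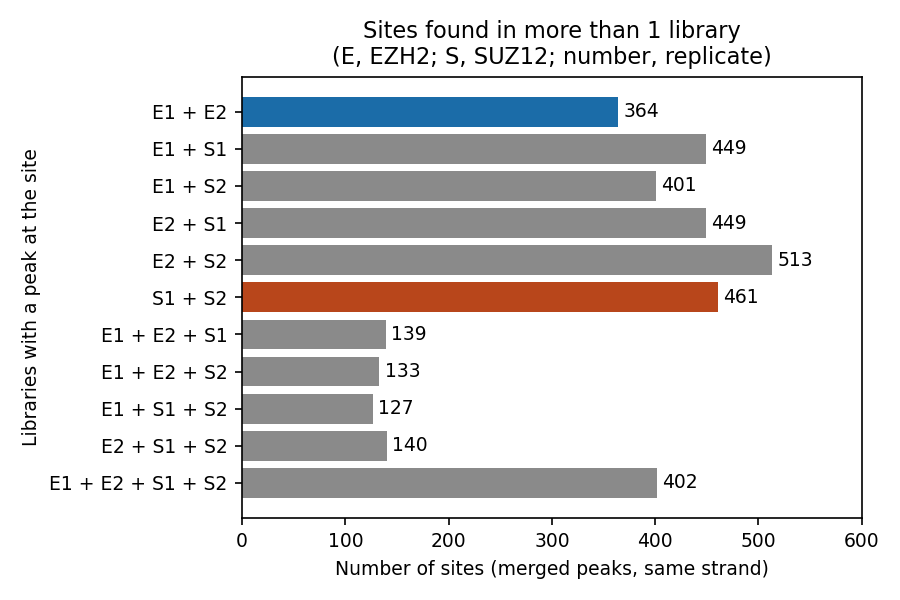
Number of merged same-strand sites (horizontal axis) for each combination of 2 or more libraries (vertical axis, E for EZH2, S for SUZ12, with the replicate number), with pairs of the same protein in blue and orange. The EZH2 pair has 364 sites, below the 401 to 513 of pairs of different proteins, the SUZ12 pair has 461, within that range, and 402 sites have all 4 libraries.

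Whether libraries of a protein resembled each other more than libraries of different proteins was asked over bases. The Jaccard index was 4.02% between the EZH2 clones and 3.97% between the SUZ12 clones, and 3.72% to 4.59% between the proteins. The mean within proteins minus the mean between proteins was -0.0359 percentage points (exact permutation test, two-sided p = 1, where 3 splits allow no p below 0.333). The sign turned when only summits were compared, at 0.139 percentage points for summits within 100 bp. Among the 100 best peaks of a library, a mean of 81% were found in the other clone of the same protein and 84.5% in a library of the other protein.

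Regional numbers of peaks were compared between the proteins in 846 windows of 1 Mb. No window passed an adjusted p of 0.05 in limma, and 38 had an unadjusted p under 0.05 where 42.3 would be reached by chance. The window with the smallest adjusted p, 0.212 in limma, lay on the minus strand of chromosome 8 at 26000001 to 27000000. It held 5 and 3 EZH2 peaks and 10 and 19 SUZ12 peaks, a log2 difference of 1.60 ± 0.44 (SE). The median half-width of the 95% interval of a window was 0.87 on the log2 scale, or 1.82-fold, before adjustment for the number of windows. In simulated windows the adjusted test called 38% of 2-fold and 89.8% of 4-fold differences. That simulation held many changed windows, some by 16-fold, which eases the adjusted threshold, and clones varied by Poisson noise alone. Its shares therefore do not give the power for few changed windows, which would be lower. Many differences of about 2-fold, and possibly larger ones, were not detectable with these numbers of peaks.

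Chromosome X, on which PRC2 acts in female cells that inactivate 1 copy, carried few peaks for its length in every library. Its share was 3.35% and 3.84% in the EZH2 libraries, a mean of 3.60 ± 0.347% (SD, n = 2), and 3.56% and 3.94% in the SUZ12 libraries, a mean of 3.75 ± 0.267%, while X makes up 6.28% of the assembled length. The proteins differed by -0.148 percentage points, EZH2 minus SUZ12, which was less than the spread between clones (exact permutation test, two-sided p = 0.667, smallest possible 0.333). The sign of this difference turned when either EZH2 replicate 1 or SUZ12 replicate 2 was left out, at 0.0976 and 0.0407 percentage points, with covered bases, at 0.0368, and in the 50% of each list with the lowest FDR, where EZH2 was higher by 0.415. With a mean of 2.73 peaks per Mb over the libraries, X had the lowest density of the 20 chromosomes compared, below chromosome 3 with 3.08. Chromosome 11 had the highest density, 7.94 peaks per Mb, followed by chromosome 8 with 6.33 and chromosome 17 with 6.12. Gene content, transcription and mappability were not compared with these densities, so the low density is not shown to be a lack of PRC2-bound RNA on X. The leading X windows were on the plus strand at 98850001 to 98900000, with 4 peaks in each library, and on the minus strand at 71450001 to 71500000, with 3, 3, 6 and 3. These 2 windows were chosen after the data were seen.

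**Figure D4:**
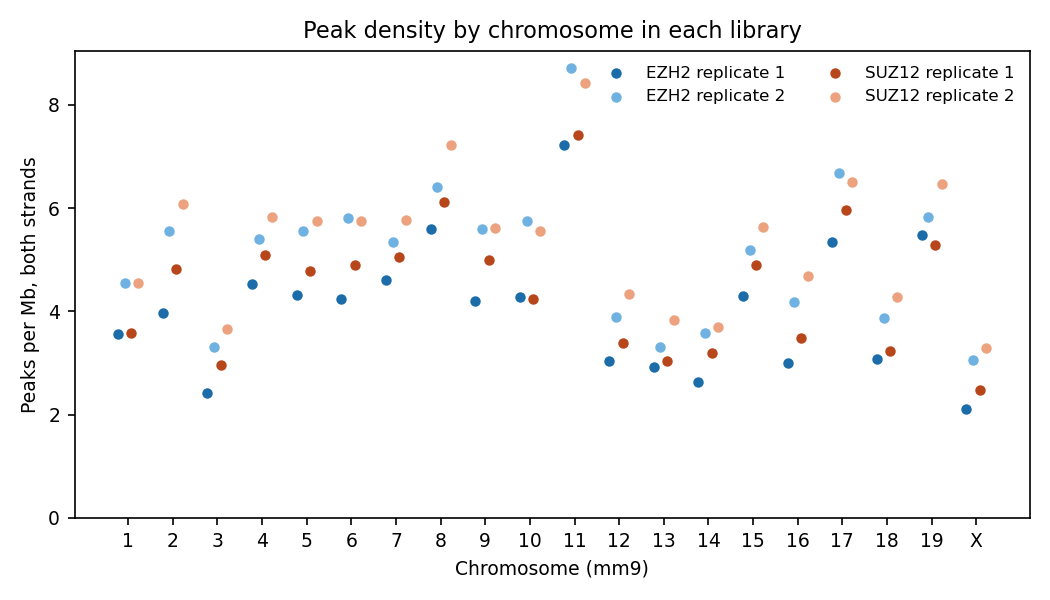
Peaks per Mb on both strands (vertical axis) for chromosomes 1 to 19 and X (horizontal axis) in each of the 4 libraries, 1 point per library. Chromosome 11 is highest with a mean of 7.94 and X lowest with a mean of 2.73.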

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

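Of the tests below, the trend with regional density and the unmatched peak widths were set before their results were seen, and the others, and the resampling by chromosome, after.

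In cells labelled female, 5 peaks lay on chromosome Y, a signal outside the chromosomes compared. Each library had 1 of them at the same place on the minus strand, within 327999 to 328251, with an FDR between 5.21e-12 and 2.46e-05, and EZH2 replicate 2 had another on the plus strand at 2077220 to 2077511. A mark for a failed FDR was carried in the names of 22 peaks, 10 in EZH2 replicate 1 and 12 in SUZ12 replicate 1. In all, 37 peaks ended on a multiple of 10 kb, where 4.93 would by chance and 0 started on one, and 26 of the 28 peaks wider than 3 kb were among them.

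Clones of a protein shared few peaks, and chance sampling of independent reads is argued against for strong peaks and stays open for weaker ones. Of 1071 peaks with p of at most 1/2^30, 61.9% (Wilson interval 59.0 to 64.8%) were found in the other clone, and of the remaining peaks 7.54%. An assumed 0.5 of the depth and 1 independent read per halving of p would give 99.8% for the former. The lists do not show the depth, but a clone read at least as deep as the other should exceed that share. The share was low in both directions, at 64.0% and 62.3% for EZH2 replicates 1 and 2 and 62.8% and 59.5% for SUZ12. With p from 1/2^20 to 1/2^30 it was 17.2 to 28.1%, against 92.6 to 93.0%. These values argue against chance sampling of independent reads as the whole reason for these peaks. Whether reads are copies is not shown. Displacement by up to 1 kb is argued against as the whole reason, since 16.6% of all peaks had a same-strand peak of the other clone within that distance, but it was not excluded for part of the peaks, and wider displacement stays open. Copies of few molecules amplified in 1 library may contribute and cannot be told apart, as strong peaks found in no other library were narrower in 4 of 4 libraries but also weaker, and 53.9% (47.3 to 60.4%) were narrower than a shared peak of similar p, with 13 of 40 in SUZ12 replicate 1 against 15 of 27, 36 of 61 and 54 of 91 in EZH2 replicates 1 and 2 and SUZ12 replicate 2, while differences between the clones in the RNA bound stay open and untested.

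Same-numbered libraries of different proteins gave the highest and the lowest Jaccard index of the 6 pairs, 4.59% for replicates 1 and 3.72% for replicates 2, so their mean of 4.15% against 3.95% for the other pairs rests on replicates 1, while 83 of 846 windows had an unadjusted p under 0.05 in limma between the numbers, 38 between the proteins and 21 in the remaining split, where 42.3 would by chance, with 0 past the adjusted threshold in any. The gap in means was 0.170 percentage points at equal list lengths and 0.204 with all peaks, so equal lengths did not remove it. As its 2 same-numbered pairs lie so far apart, a gap of this size does not decide on unequal lengths as a reason. A trend with regional density, as depth might give, stays open: deviations of same-numbered libraries across windows correlated at 0.117, and at 0.0750 after the trend was removed, with an interval of -0.00056 to 0.145 when the 20 chromosomes were resampled. Of the 3 splits of the libraries, 1, the split by number itself, gave a within-minus-between difference of 0.204, the highest other being 0.168 in size, and 3 splits are too few to weigh chance. A shared day or preparation of same-numbered libraries stays open, since the labels name none, and no biological explanation was tested.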

How the results depend on the processing

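Clone sharing stayed above chance in all 8 same-strand alternatives for each protein, at 6.27 to 10.2% for EZH2 and 6.15 to 9.82% for SUZ12. On the opposite strand the EZH2 share was 0.132%, within chance, as the strand itself was changed, and the SUZ12 share of 0.138% passed the highest of its own 100 placements, 0.135%, but not of those drawn without chromosome M, 0.190%. Consensus sites in common stayed above chance in all 12 same-strand alternatives. With a library left out the share was 25.5 to 28.2%, where all peaks of the remaining library stood in for that protein's consensus sites. On the opposite strand it was 0.469%, above the highest of 100 random placements, 0.188%. Local shifts were not run for the opposite strand. On the same strand the highest of 100 local shifts of these sites was 0.657%, so the opposite-strand share is not shown to pass local chance. The within-minus-between difference turned positive for summits within 100 bp (0.139) and peaks set to 100 bp (0.142), which are nearly the same setting. It kept its sign in 7 alternatives. Among them, that without chromosome M could not change it, and on the opposite strand it was only -0.0044. At 50% reciprocal overlap it was computed on shares of peaks in place of bases. The cause was not tested. No window passed 0.05 in limma in any of 13 alternatives, with a smallest adjusted p of 0.0973 to 0.992, where a lone library was assumed to vary like the others. The X difference turned positive for covered bases (0.0368) and for the 50% of each list with the lowest FDR (0.415), and ranged from -0.393 to 0.0976 with a library left out, where the protein with 1 library gave a value with no spread. The cause was not tested. Leaving out peaks that end on a multiple of 10 kb, chosen after the data were seen and run for the overlap results only, kept both clone shares and the consensus sites in common above chance and gave a within-minus-between difference of -0.0624.

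With the replicate number as a block, 0 windows passed and the overlap difference was -0.160. The X difference stayed at -0.148 by construction, since the mean of the differences within numbers equals the difference of the means. Deviations of same-numbered libraries correlated at 0.117, but 2 pairs of clones share only a number. Alternatives for locations in genes, gene lists and sequence were not run. Those without chromosome M left the observed values unchanged because 0 peaks lay there, and only the random placements, drawn anew, differed. The number of peaks limits all comparisons, and read depth was not known.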

Other observations

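The tests in this part were all chosen after the results were seen.

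Peaks found in 1 library only lay near peaks of other libraries more often than under placement over whole chromosomes. Of such peaks, 67.4% in EZH2 replicate 1, 63.0% in EZH2 replicate 2, 67.7% in SUZ12 replicate 1 and 62.7% in SUZ12 replicate 2 had a peak of another library on the same strand within 10 kb, where random placement gave 13.5 to 14.9%. On the opposite strand the shares were 9.84%, 7.76%, 9.13% and 8.21%, below the level of random placement. Placement covered transcribed and untranscribed sequence alike, so the gap does not separate binding by the subunits from the presence of RNA in a region. Numbers of peaks per 1-Mb window correlated between libraries with a Pearson r of 0.793 to 0.828 across 3803 windows, which are not independent replicates.

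Some of the strongest sites found in both clones of a protein and in no library of the other had peaks of the other protein within 10 kb, and others had none. For EZH2, sites on the minus strand of chromosome 1 at 24621236 to 24621402 and on the plus strand of chromosome X at 100643235 to 100643655 had an FDR of at most 1.76e-08 and 1.89e-07 in both clones, with 6 and 3 SUZ12 peaks within 10 kb. The chromosome 1 site lay between same-strand sites found in all 4 libraries, at 24618674 to 24619380 and at 24621800 to 24622217, so its stretch was not particular to EZH2. For SUZ12, a site on the minus strand of chromosome 4 at 155552074 to 155552453 had an FDR of at most 1.91e-08 with 5 EZH2 peaks within 10 kb. SUZ12 sites on the plus strand of chromosome 5 at 123516411 to 123516709 and on the minus strand of chromosome 18 at 70631973 to 70632305 had at most 4.32e-08 and 1.11e-07, with 0 EZH2 peaks within 10 kb. An FDR below 1e-05 in both libraries was reached at 9 EZH2-only and 17 SUZ12-only sites, and at 9 to 18 sites of pairs of different proteins.

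Peaks on both strands at the same place were rare, at 0.153%, 0.136% and 0.138% of peaks in EZH2 replicates 1 and 2 and SUZ12 replicate 1. SUZ12 replicate 2 had 0.229%, or 32 of its 13951 peaks, above the highest of 100 random placements, 0.136%, and of 100 local shifts, 0.201%.

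Between 97.5% and 97.9% of the p-values in each library were powers of 1/2 within 0.0001 on the log2 scale, the largest being 1/2^7, which 14.7 to 18.1% of peaks had. A candidate explanation is a binomial test of library reads against control reads of equal weight, in which a peak with 7 reads and no control read would get 1/2^7. Of the 331 other p-values of SUZ12 replicate 2, 83.4% equalled a binomial tail for 7 to 199 library reads and 1 to 59 control reads within a relative 2e-06, against 0.0504% of the same values moved by up to 0.7%. The other libraries gave 78.3%, 83.0% and 80.5%. Under this hypothesis nearly all peaks would have no control read, and no biological explanation was tested.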
